A study of Homo sapiens with 12 samples.

How the data were processed

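Small RNA was sequenced from human bone marrow mesenchymal stromal cells (MSCs), the fibroblast-like progenitors of bone, cartilage and fat, and from the extracellular vesicles (EVs) they released. The cells were left untreated or exposed to 0.3 U/mL sphingomyelinase (SMase) for 24 h. SMase is an enzyme that splits sphingomyelin into ceramide and phosphorylcholine, and ceramide is a lipid tied to vesicle budding. Per the labels, RNA was taken with a miRNeasy kit and libraries were made with a QIAseq miRNA kit. There were 4 groups of 3 libraries: untreated cells, SMase-treated cells, EVs of untreated cells and EVs of SMase-treated cells. Group and replicate number came from the labels, which do not say that the replicates were separate cultures. The p-values therefore measure the spread between these samples, which may be technical. In cells that spread was pooled across miRNAs.

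The authors deposited raw counts in a table for the cells and a table for the EVs, each with 30332 named small RNAs. Of these, 2632 were mature microRNAs (miRNAs) and 27700 carried names of PIWI-interacting RNAs (piRNAs), and 1030 miRNAs and 1584 piRNA names had any count. A blank-named entry held 0 counts and was left out. The aligner, the genome build, the annotation version, and whether counts were of reads or of molecular identifiers were not given in the sources used here. No coordinates are given for that reason. Intervals and floors cover counting error only. Relatives with near-identical sequences, such as let-7 members, miR-23a and miR-23b, or miR-320 members, can trade reads in the authors' counting, so single-member values in these families are uncertain. Of the 50 most abundant piRNA names in EVs, 8 had a partner within 2% of their count in all 6 EV libraries. Whether such names share sequence was not tested.

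Total counts ranged from 538086 to 1147273 in cells and from 377729 to 583940 in EVs. The miRNA part of the untreated EV libraries was small, 8796 to 11534 counts, against 66657 to 86432 in SMase EVs and 498538 to 1082593 in cells. Depth therefore limited what could be seen in untreated EVs. Replicate libraries of a group were compared for duplicates. The lowest chi-square per degree of freedom for a pair was 2.49, so no library was a repeat of another of its group within sampling noise. Pairs across groups were not compared.

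Differential abundance was tested on the deposited miRNA counts with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr with its minimum count of 10, the quasi-likelihood F test (two-sided) and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. The SMase effect was fitted in the 6 cell libraries and in the 6 EV libraries apart. Each miRNA had 1220 degrees of freedom in the cell fit, against 9.26 in the EV fit, so the cell test used a spread shared across miRNAs. Cell p-values and SEs thus do not reflect the spread of a single miRNA between its own libraries. EVs were set against cells, and the difference of the SMase effects (EVs minus cells, an interaction term) was taken, in a fit of all 12 libraries. Levels are CPM (counts scaled to a common library total of miRNA counts, edgeR units) after TMM scaling. All these values are relative to the miRNA counts of a library, so they give shares of the miRNA pool, not amounts per vesicle or per cell. A miRNA at 0 in a group was given a bound from a floor of 3 counts over the group, written as "at least". The count in the other group was taken as exact, so a bound from few counts is uncertain.

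Before the data were examined, 23 lists of miRNAs were fixed, with 214 entries in all, as were the tests, the alternatives and the rule for names. The lists were the let-7, miR-15/16, miR-29, miR-30, miR-34, miR-181 and miR-320 families, the miR-17/92 and miR-23/27/24 clusters, miR-10, miR-99, miR-125 and miR-196 miRNAs, the 14q32 imprinted cluster, mesenchymal and smooth muscle miRNAs, bone, cartilage and fat differentiation, inflammation, hypoxia and angiogenesis, miRNAs whose release was tied to neutral sphingomyelinase, and miRNA names that overlap fragments of other RNAs such as ribosomal RNA. Lists for the 19q13 placental cluster, blood cells, liver, epithelium, skeletal and heart muscle, and neural cells covered other sources of RNA. Lists with at least 3 tested members were tested with limma 3.58.1 camera (preset correlation 0.01, log2 CPM with a prior count of 2), again with an estimated correlation, and with fry. The rule named, per comparison, the 8 largest rises and 8 largest falls past the threshold with a mean CPM of at least 10 and no overlap between groups, the 6 most abundant past the threshold, the 2 most abundant members of each tested list, and the called members of lists that passed. In the description of the data, the 10 most abundant miRNAs of a group could be named.

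Library composition was compared with exact two-sided permutation tests, for which the smallest possible p with 3 against 3 is 0.1, adjusted over 24 tests. Alternatives comprised DESeq2 1.42.0 size factors and Wald test, upper-quartile factors, total miRNA counts, limma-voom, no filter or a mean CPM of at least 10, an adjusted p under 0.1, a minimum log2 fold change of 1, all piRNA and miRNA names in a single test, replicate blocks, another set of fitted libraries, and each library left out in turn. Thinning of the SMase EV libraries to 10324 miRNA counts, scaling of all names by total counts, a block across compartments, and a test without the fragment list were added after the data had been seen. Plots were drawn with matplotlib 3.10.9.

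The procedure was tested on simulated counts with 200 changed miRNAs, drawn 10 times per comparison. All simulated miRNAs had a common spread, and rises and falls were equally many. Where the spread differs between miRNAs, the recovered shares may be too high. For EVs against cells, all simulated libraries were drawn from 1 averaged profile, so the large difference between the compartments was absent. Simulations for fits of all 12 libraries used a spread (edgeR dispersion) of 0.0214, against 0.0408 for EVs and 0.0156 for cells fitted apart. Recovered and false shares of these comparisons may therefore not hold for the real data. For cells (mean of 310.8 miRNAs tested), 90.8% of 2-fold and 99.7% of 4-fold changes were recovered. For EVs (118.4 tested), the shares were 59.6% and 94.3%. For EVs against cells they were 32.7% and 62.6% without treatment (268.9 tested) and 70.4% and 96.2% with SMase (251.0 tested). For the difference of effects (276.4 tested) they were 18.3% and 44.1%. False calls made up 3.73% of calls in cells and 3.23% in EVs. They made up 8.59% and 3.70% for EVs against cells without and with SMase, and 9.45% for the difference of effects. With no change simulated, the 10 draws together gave 12 calls for the difference of effects and at most 1 in each other comparison. The median log2 value under TMM then lay at -0.12 for untreated EVs against cells and at 0.34 for the difference of effects. Under total miRNA counts it lay at -0.01 and 0.01. TMM over all 12 libraries was thus shifted in these simulations, and differences of effects near that size are uncertain. The cause of the shift was not tested.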

Results

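Small RNA counts were available for 12 libraries of MSCs and their EVs, 3 in each of 4 groups. The series title names vesicle biogenesis, cargo sorting and potency as its subjects, and the comparisons below set SMase against no treatment in cells and in EVs, and EVs against cells. let-7 miRNAs, which restrain LIN28 and RAS and accumulate in differentiated cells, led every group. In untreated cells let-7a-5p made up 15.6% ± 1.30 and let-7b-5p 14.5% ± 2.00 of miRNA counts (SD, n = 3), followed by miR-21-5p at 4.21% ± 0.390, the p53-induced miR-34a-5p at 4.13% ± 0.0630 and the collagen-repressing miR-29a-3p at 3.91% ± 0.260. In untreated EVs let-7b-5p came first at 23.5% ± 1.04, then let-7a-5p at 15.8% ± 2.41 and let-7f-5p at 3.89% ± 0.549. In SMase EVs let-7a-5p came first at 22.9% ± 0.237, then let-7b-5p at 21.6% ± 1.28, let-7f-5p at 5.22% ± 0.163 and miR-320a-3p at 4.51% ± 0.215.

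Markers of other cell types were scarce. The highest count of any member in any library was 1 for the 19q13 placental cluster, 8 for epithelium, 23 for liver (miR-194-5p) and 26 for blood cells (miR-486-5p). Among neural miRNAs miR-128-3p, which many cell types express, reached 605, and among muscle miRNAs miR-1-3p reached 238, in an SMase EV library. These marker miRNAs were picked out after their values were seen.

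The share of miRNAs among the small RNA counts of EVs was higher after SMase. If the replicates of a group came from a single culture, treatment and culture cannot be told apart. miRNAs held 2.55% ± 0.233 of counts in untreated EVs and 15.03% ± 1.86 in SMase EVs (SD, n = 3 each), a ratio of 5.89, with the remainder under piRNA names. All 3 treated libraries lay above all 3 untreated libraries (exact permutation p = 0.1, the smallest this design allows, adjusted p = 0.16 over 24 tests). In cells miRNAs held 94.3% ± 0.261 of counts without and 93.6% ± 0.818 with SMase (exact permutation p = 0.2, adjusted p = 0.3). Per piRNA count, miRNA counts were 6.74-fold higher in SMase EVs (log2 2.75, SE 0.141) and 0.878-fold in SMase cells (log2 -0.19, SE 0.118). The effects in EVs and cells lay 2.94 apart on the log2 scale (exact permutation within compartments, p = 0.01, 4 of 400 arrangements as large). That p is for no effect in either compartment, not for equal effects, and rests mostly on the EV effect. The number of miRNAs with at least 10 counts was 69.7 ± 5.51 in untreated and 139 ± 8.74 in SMase EVs, but 65.7 ± 0.577 once SMase EVs were thinned to the miRNA depth of untreated EVs. The 10 most abundant miRNAs held 64.0% ± 2.73 and 68.6% ± 1.31 of EV miRNA counts (exact permutation p = 0.1, adjusted p = 0.16). They held 57.1% ± 0.604 and 57.5% ± 0.410 of cell miRNA counts, and 305 ± 19.6 and 292 ± 23.2 miRNAs had at least 10 counts in cells.

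**Figure D1:**
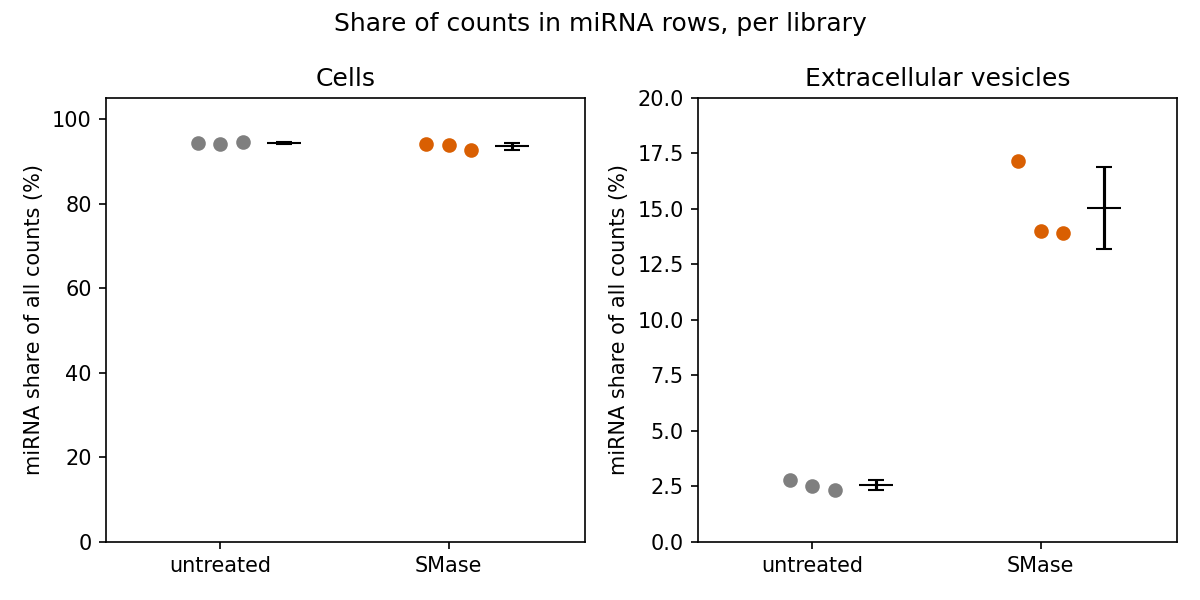
Share of all counts held by miRNAs (%, linear axes from 0, a separate scale for cells and EVs) in each of the 12 libraries, with group means and SDs beside the points. The 3 SMase EV libraries lie between 13.9% and 17.2%, above the untreated EV libraries at 2.33% to 2.79%, while the cell groups lie at 94.3% and 93.6%.

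As shares of the EV miRNA pool, let-7a-5p, 3 other let-7 members and miR-320a-3p rose after SMase, while let-7g-5p, miR-16-5p and miR-24-3p were among those that fell. let-7a-5p rose from 153574 ± 29862 to 243228 ± 11810 CPM (log2 fold change 0.66, SE 0.15, SD of CPM, n = 3 per group, edgeR adjusted p = 0.0151). miR-320a-3p, a miRNA made without Drosha, rose from 30748 ± 702 to 47888 ± 4942 CPM (0.64, SE 0.11, edgeR adjusted p = 0.00514). let-7g-5p fell by 0.69 (SE 0.09, edgeR adjusted p = 0.00195), from 36216 ± 1742 to 22392 ± 739 CPM. Of 110 miRNAs tested, 20 passed the threshold, 7 higher and 13 lower, and in all 20 the groups did not overlap. Groups did not overlap for 38 of the 110, where chance gives 10%.

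In the let-7 family, 4 of 9 tested members rose and 1 fell (4 and 2 when adjusted over the list alone): let-7e-5p by 0.84 (SE 0.18), let-7d-5p by 0.71 (SE 0.12), let-7a-5p, and let-7f-5p by 0.55 (SE 0.13), against let-7g-5p. let-7b-5p stood at 0.01 (SE 0.12). As a set the family did not pass (limma camera adjusted p = 0.723). The miR-320 family had 1 riser among 3 tested members, miR-320a-3p (1 when adjusted over the list alone), with miR-320b at 0.55 (SE 0.34, edgeR adjusted p = 0.414). Camera gave an adjusted p of 0.304 for the family and limma fry an adjusted p of 0.00714. In the miR-23/27/24 clusters miR-23b-3p rose by 2.76 (SE 0.65, edgeR adjusted p = 0.0192), from 65.3 ± 57.4 to 445 ± 48.9 CPM (2 and 98 counts summed over 3 libraries), while miR-24-3p fell by 0.45 (SE 0.10) and miR-23a-3p stood at 0.19. miR-1268a rose by 3.18 (SE 0.96, edgeR adjusted p = 0.048), from 58.6 ± 102 to 601 ± 356 CPM (2 counts in untreated EVs, both in a single library).

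Of the names that overlap fragments of other RNAs, 5 of 7 tested members fell (5 when adjusted over the list alone). The list passed limma camera (adjusted p = 0.00427, adjusted p = 0.809 with an estimated correlation) but not fry (adjusted p = 0.0815). They were miR-4516 (-1.81, SE 0.23), miR-4488 (-1.24, SE 0.21), miR-3960 (-2.01, SE 0.36), miR-4508 (-1.69, SE 0.42) and miR-4492 (-2.28, SE 0.54). Their direction depended on the scaling: per piRNA count the median change of the 7 was 0.92, above 0 in all 7, whereas with piRNA counts in the TMM scaling miR-4516 (-0.68) and miR-3960 (-0.89) were still called lower. Their share of EV miRNA counts was 3.42% ± 1.13 without and 1.10% ± 0.0872 with SMase (exact permutation p = 0.1, adjusted p = 0.16). miR-138-5p, a brake on bone formation by MSCs, fell by 1.02 (SE 0.22), miR-29a-3p by 0.73 (SE 0.19) and miR-889-3p of the 14q32 cluster by 1.78 (SE 0.47). miR-16-5p, a cell cycle regulator whose release was tied to neutral sphingomyelinase, fell by 0.39 (SE 0.11, edgeR adjusted p = 0.0371), the only 1 of 4 tested members of its export list to pass, with miR-100-5p at 0.10 (SE 0.12). It was also the only 1 of 4 in the miR-15/16 family.

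The remaining EV lists did not pass camera. Passing members numbered 0 of 3 for the miR-17/92 clusters (miR-93-5p 0.17), 0 of 5 for the miR-30 family (miR-30d-5p 0.23), 0 of 8 for miR-10, miR-99 and miR-125 miRNAs (miR-10a-5p -0.26) and 0 of 5 for mesenchymal miRNAs (miR-143-3p 0.17, miR-199a-3p -0.35). They numbered 0 of 6 for hypoxia and angiogenesis (miR-221-3p 0.03, miR-130a-3p -0.17), 1 of 4 for bone, cartilage and fat (miR-138-5p), 1 of 7 for inflammation (0 when adjusted over the list alone, miR-21-5p -0.07) and 1 of 10 for the 14q32 cluster. The miR-29, miR-34 and miR-181 families had under 3 tested members, with 1 of 2, 1 of 1 and 1 of 2 lower. Adjusted over the list alone, passing counts were otherwise the same in every EV list.

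These EV directions are shares of the miRNA pool. When piRNA counts entered the scaling, the median miRNA moved by 1.20 (log2), 90 of 119 tested miRNAs were higher and 2 lower, and 7 of the 13 lower calls turned positive, 3 of them past the threshold, miR-16-5p at 0.75, miR-24-3p at 0.69 and let-7g-5p at 0.45. On miRNA counts alone the balance also turned, to 20 higher and 8 lower with upper-quartile factors, 16 and 8 with a mean CPM of at least 10, 11 and 7 with no filter, and 13 and 9 with all libraries fitted together. The number of calls fell from 20 to 6 without EVs untreated replicate 2, to 7 without EVs untreated replicate 3 and to 9 without EVs SMase replicate 2. let-7d-5p, miR-320a-3p, let-7g-5p, miR-4488 and miR-4516 kept their calls without any single library. let-7a-5p lost its call without EVs untreated replicate 2 (adjusted p = 0.0504) or replicate 3 (adjusted p = 0.058), and miR-23b-3p likewise (0.0799 and 0.052, edgeR).

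**Figure D2:**
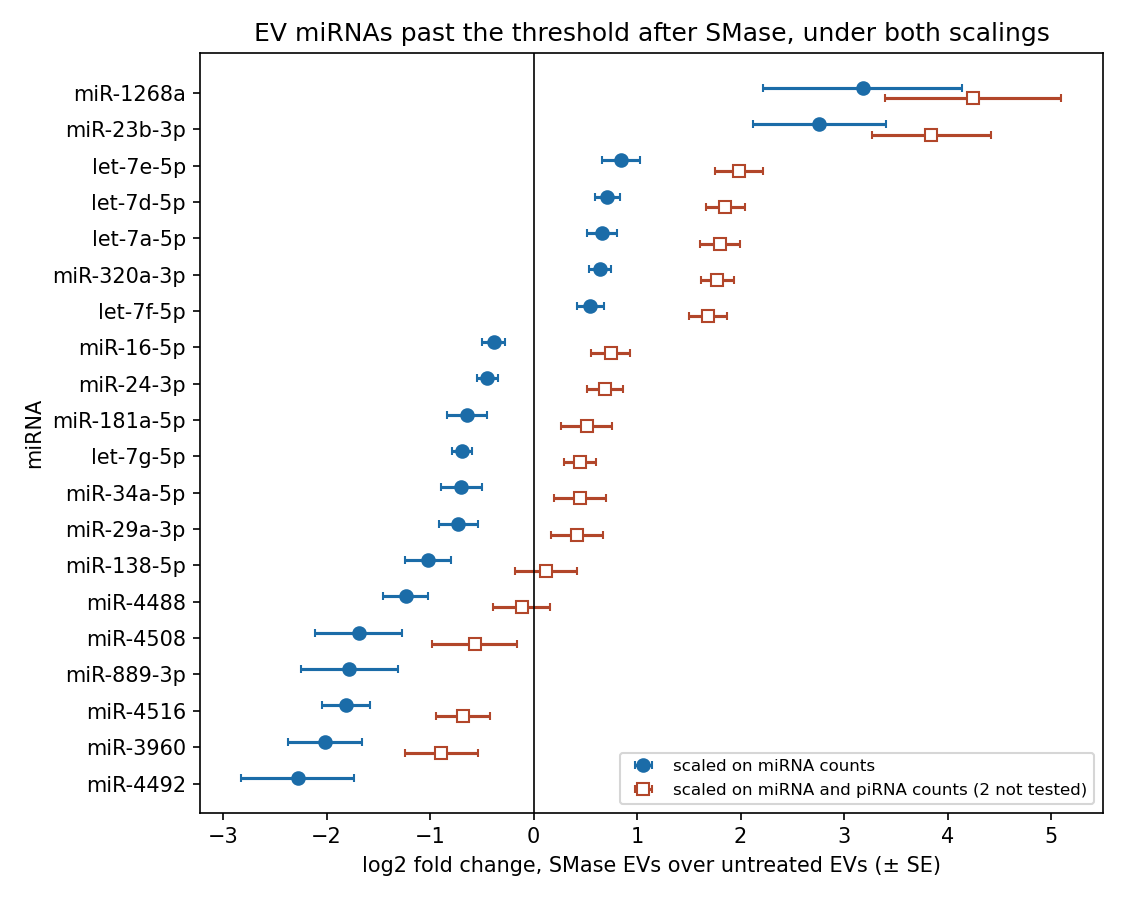
log2 fold change (SMase EVs over untreated EVs, with SE, 3 libraries per group) of the 20 EV miRNAs past the threshold, scaled on miRNA counts (filled circles) or on miRNA and piRNA counts together (open squares). let-7a-5p stands at 0.66 under the former and 1.80 under the latter, and let-7g-5p at -0.69 and 0.45.

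In cells, miR-143-3p, miR-4455 and miR-21-3p rose after SMase and miR-29b-3p fell. miR-143-3p, from the smooth muscle and mesenchymal miR-143/145 cluster, rose from 12421 ± 1817 to 20572 ± 1213 CPM (log2 fold change 0.73, SE 0.13, SD of CPM, n = 3 per group, edgeR adjusted p = 2.86e-06). miR-4455 rose from 460 ± 49.96 to 886 ± 101 CPM (0.95, SE 0.15, edgeR adjusted p = 8.37e-08). miR-21-3p, the minor arm of the miR-21 precursor, rose from 1606 ± 42.9 to 2484 ± 66.4 CPM (0.63, SE 0.13, edgeR adjusted p = 0.000205), while the major arm miR-21-5p lay at 41712 ± 5255 and 41680 ± 2962 CPM (adjusted p = 0.993). The collagen-repressing miR-29b-3p fell by 0.65 (SE 0.13, edgeR adjusted p = 0.000107), from 2646 ± 442 to 1684 ± 83.6 CPM.

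Of 305 miRNAs tested, 17 passed, 8 higher and 9 lower, and in 13 of the 17 the groups did not overlap. Groups did not overlap for 49 of the 305, where chance gives 10%. The balance leaned higher under other settings: 8 higher and 3 lower with upper-quartile factors, 7 and 4 with DESeq2 size factors, 4 and 2 with total miRNA counts, 4 and 1 with all libraries fitted together, and 3 and 1 with all names, against 5 and 6 with no filter. The other risers were miR-4458 by 1.60 (SE 0.49), miR-27a-5p by 1.25 (SE 0.29), miR-3182 by 0.99 (SE 0.25, but 0.41 with edgeR adjusted p = 0.617 without SMase replicate 3), miR-145-3p by 0.88 (SE 0.26) and miR-3195 by 0.81 (SE 0.26). miR-335-5p, encoded in an intron of MEST, fell by 0.96 (SE 0.30), miR-214-3p by 0.60 (SE 0.16), miR-503-5p by 0.42 (SE 0.13), miR-15b-5p by 0.39 (SE 0.13) and miR-181a-5p by 0.42 (SE 0.13, groups overlapping).

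None of the 17 tested lists passed camera in cells (0 of 17, 0 with an estimated correlation and 0 by fry; 0 lists at an unadjusted camera p under 0.05). Of the mesenchymal list, 2 of 7 rose (miR-143-3p and miR-145-3p) and 1 fell (miR-214-3p). Of the miR-15/16 family 2 of 7 fell (miR-15b-5p and miR-503-5p), while miR-16-5p stood at 0.28 (SE 0.13). The miR-29 family had 1 of 4 lower (miR-29b-3p), with miR-29a-3p at -0.03. The miR-181 family had 1 of 3 lower, the miR-17/92 clusters 1 of 8, inflammation 1 of 8, hypoxia and angiogenesis 1 of 9, and bone, cartilage and fat 1 of 9 (miR-335-5p). No member passed in the let-7 family (0 of 9, let-7a-5p 0.16, let-7b-5p -0.08), the miR-320 family (0 of 4, miR-320a-3p -0.02), miR-10, miR-99 and miR-125 miRNAs (0 of 9), the miR-30 family (0 of 7), the miR-34 family (0 of 3, miR-34a-5p -0.10), the miR-23/27/24 clusters (0 of 5), the export list (0 of 4), the 14q32 cluster (0 of 21) or the fragment list (0 of 3). Adjusted over the list alone the counts were the same, except that the 1 tested blood cell miRNA passed.

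The cell count rested on single libraries: it was 6 without untreated replicate 1, 11 without untreated replicate 2, 4 without SMase replicate 1, 4 without SMase replicate 2, 9 without SMase replicate 3 and 23 without untreated replicate 3. miR-143-3p, miR-4455 and miR-21-3p kept their calls without any single library. With all names in the test miR-21-3p lost its call (edgeR adjusted p = 0.0568), and miR-143-3p and miR-4455 each stood at an edgeR adjusted p of 0.036. miR-27a-5p lost its call without SMase replicate 2 (edgeR adjusted p = 0.0926) and miR-29b-3p without SMase replicate 1 (edgeR adjusted p = 0.133).

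The measured changes in EVs showed little relation to those in cells, though noise in both sets of changes can hide a relation. Across 103 miRNAs tested in both, which are not independent of each other, the log2 changes had r = 0.089 and rho = 0.104, and 54 had the same sign. miR-181a-5p was lower in both, against 0.699 expected by chance, and 0 miRNAs were higher in both. No library is shared between these effects. The sign of r turned without Cells SMase replicate 1 (-0.018), EVs SMase replicate 2 (-0.021) or EVs SMase replicate 3 (-0.134).

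**Figure D3:**
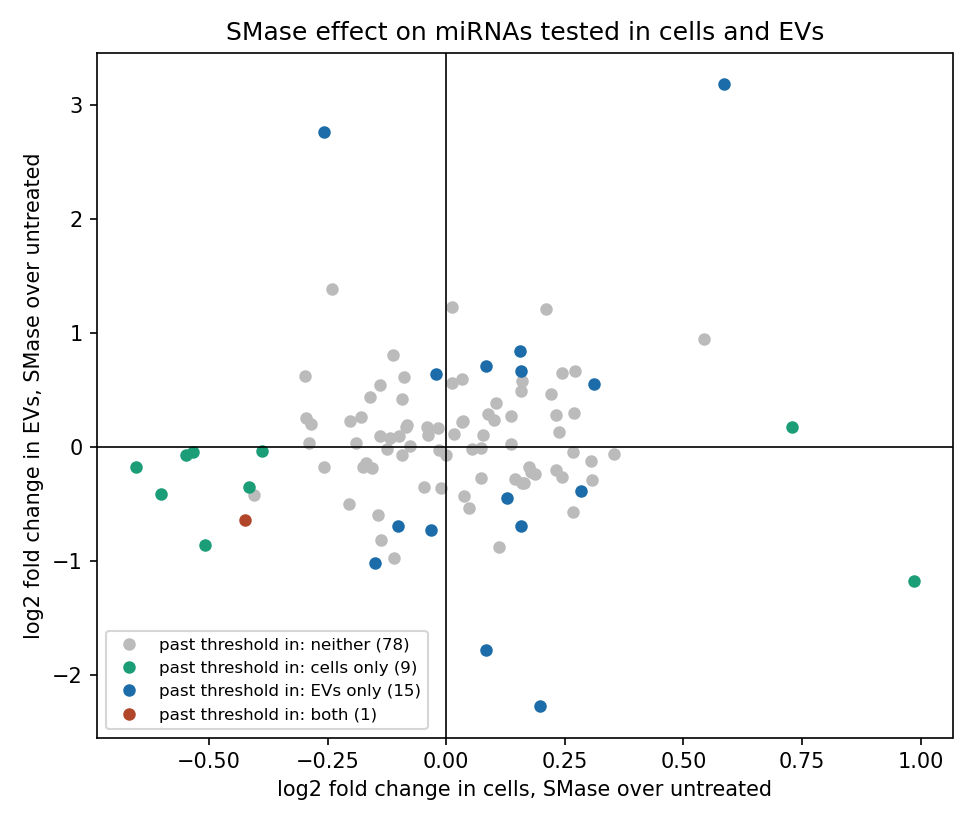
log2 fold change after SMase in cells (horizontal) and in EVs (vertical) for the 103 miRNAs tested in both. Coloured points passed the threshold in cells only (9), in EVs only (15) or in both (1, miR-181a-5p), and r over all points is 0.089.

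The difference of the SMase effects asked which miRNAs moved differently in EVs and cells. miR-23b-3p (3.20, SE 0.69), miR-320a-3p (0.80, SE 0.18, edgeR adjusted p = 0.0162), let-7e-5p (0.82, SE 0.20), let-7d-5p (0.77, SE 0.19), let-7a-5p (0.65, SE 0.18), miR-31-5p (0.69, SE 0.17) and miR-99a-5p (1.76, SE 0.50) had a more positive effect in EVs than in cells. The value of miR-99a-5p rested on 6 counts summed over the untreated EV libraries. miR-31-5p passed in neither compartment alone (EVs 0.25, edgeR adjusted p = 0.153, cells -0.29, edgeR adjusted p = 0.255). let-7g-5p (-0.71, SE 0.17), miR-4516 (-2.34, SE 0.54), miR-4492 (-2.39, SE 0.67) and miR-3182 (-2.03, SE 0.57) had a more negative effect in EVs. For miR-143-3p, which rose in cells and stood at 0.17 in EVs, the difference was -0.42 (SE 0.21, edgeR adjusted p = 0.296), so its effects were not shown to differ. Of 264 miRNAs tested, 11 passed, 7 positive and 4 negative, all at edgeR adjusted p of 0.0162 to 0.0405.

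The fragment list was lower in this difference (2 of 9 members passed, 2 when adjusted over the list alone, camera adjusted p = 0.000278, adjusted p = 0.992 with an estimated correlation, fry adjusted p = 0.0757). No other list passed camera. Passing members were 3 positive and 1 negative of 9 for let-7, 1 of 4 for miR-320, 1 of 5 for miR-23/27/24, 1 of 9 for miR-10, miR-99 and miR-125 miRNAs, 1 of 9 for bone, cartilage and fat and 1 of 8 for inflammation (miR-31-5p in both), with 0 of 7 for miR-17/92, 0 of 7 for miR-15/16, 0 of 3 for miR-29, 0 of 7 for miR-30, 0 of 3 for miR-34, 0 of 3 for miR-181, 0 of 7 for mesenchymal, 0 of 9 for hypoxia, 0 of 4 for export and 0 of 21 for 14q32. Adjusted over the list alone, miR-23/27/24, bone, export and 14q32 gained 1 negative member each, and 14q32 also 1 positive member.

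The direction of this difference depends on the scaling. Under total miRNA counts 1 was positive and 11 negative, with miR-320a-3p at 0.57 (edgeR adjusted p = 0.0614) and let-7a-5p at 0.42 (adjusted p = 0.117) no longer called at 0.05, while miR-23b-3p, let-7g-5p, miR-3182, miR-4516 and miR-4492 kept their calls. Without Cells SMase replicate 3 miR-3182 stood at -1.43 (edgeR adjusted p = 0.172). The count was 3 without Cells untreated replicate 2, 7 without Cells SMase replicate 1 and 7 without Cells SMase replicate 2.

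Without treatment, EVs and cells held different miRNA profiles. The miR-320 family was higher in EVs: 4 of 4 tested members passed (4 when adjusted over the list alone; camera adjusted p = 0.0201, adjusted p = 0.276 with an estimated correlation), with miR-320a-3p at 30255 ± 797 CPM against 14662 ± 2243 in cells (log2 1.05, SE 0.13, SD of CPM, n = 3 per group, edgeR adjusted p = 1.62e-07), miR-320b at 1.17, miR-320c at 1.62 and miR-320d at 2.24. miR-320b, miR-320c and miR-320d rested on 11, 11 and 5 counts summed over the untreated EV libraries, and for miR-320d the groups overlapped. let-7g-5p was higher by 1.06 (SE 0.12), let-7b-5p by 0.76 (SE 0.12) and miR-26a-5p by 0.58 (SE 0.12), whereas let-7a-5p stood at 0.07 (SE 0.13). The abundant cell miRNAs miR-29a-3p (-2.36, SE 0.16), miR-125b-5p (-2.25, SE 0.19), miR-31-5p (-1.81, SE 0.13), miR-221-3p (-1.67, SE 0.14), miR-34a-5p (-1.61, SE 0.16) and miR-21-5p (-1.45, SE 0.16) were lower in EVs.

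Of 264 miRNAs tested, 109 passed, 41 higher in EVs and 68 lower, and in 102 the groups did not overlap. The balance moved with the settings on miRNA counts alone: 37.6% of these calls were higher, against 50.5% with upper-quartile factors and 18.8% with no filter. Groups did not overlap for 148 of the 264, where chance gives 10%. The fragment list led the rises with 8 of 9 members (8 when adjusted over the list alone; camera adjusted p = 3.18e-09, adjusted p = 0.177 with an estimated correlation). miR-4488 stood at 8925 ± 2839 CPM against 0.291 ± 0.505 in cells and miR-4516 at 19308 ± 6049 against 6.85 ± 0.843, with miR-3960, miR-4508, miR-1290, miR-1246, miR-4492 and miR-7704 also higher. miR-184, best known from lens and cornea, stood at 1338 ± 1091 CPM against 0.291 ± 0.505. The muscle miRNA miR-206, at 0 in untreated cells, was at least 176-fold higher in EVs by that floor. The bound rests on 6 counts in untreated EVs and is uncertain.

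The other lists did not pass camera, and the median of all tested miRNAs was -0.46. That median ranged from -1.07 (without EVs untreated replicate 2) to -0.21 (without Cells untreated replicate 2) and was 0.002 with limma-voom. The miR-29 family had 3 of 3 lower, the miR-15/16 family 5 of 7 lower (miR-424-5p -1.74) and 1 higher (miR-16-5p 0.54), hypoxia and angiogenesis 6 of 9 lower (miR-130a-3p -1.10), inflammation 5 of 8 lower and 1 higher, and bone, cartilage and fat 4 of 9 lower and 2 higher. miR-10, miR-99 and miR-125 miRNAs had 4 lower and 2 higher of 9, 14q32 5 lower and 3 higher of 21 (miR-127-3p -2.16), mesenchymal miRNAs 2 lower (miR-199a-3p -0.89) and 1 higher (miR-143-3p 0.66) of 7, and the let-7 family 3 higher and 1 lower of 9 (camera adjusted p = 0.0671). The miR-17/92 clusters had 2 of 7 lower, miR-23/27/24 2 of 5, miR-181 2 of 3 (miR-181a-5p -0.65), miR-34 1 of 3, miR-30 1 lower (miR-30d-5p -0.47) and 1 higher of 7, and export 1 lower and 1 higher of 4. Adjusted over the list alone these counts were the same. Several cell miRNAs had 0 counts in untreated EVs, for which depth allows bounds alone: miR-299-5p was at least 6.96-fold lower, miR-4455 at least 4.82-fold, miR-497-5p at least 3.37-fold, miR-136-3p at least 2.25-fold, miR-487b-3p at least 2.04-fold, miR-652-3p at least 2.02-fold, miR-345-5p at least 1.58-fold and miR-3196 at least 1.43-fold.

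With piRNA counts in the scaling, where the median miRNA stood at -2.54, 12 miRNAs were higher in EVs and 217 lower, and 16 of the 41 higher calls became lower calls: miR-320a-3p (-0.85), let-7g-5p (-0.83) and let-7b-5p (-1.14) turned below 0, while miR-4516 stayed at 9.50 and miR-4488 at 12.01. Without EVs untreated replicate 1 the calls of miR-26a-5p (0.23), miR-143-3p (0.42), miR-16-5p (0.24), miR-320c (1.32) and miR-320d (1.87) were lost, and without replicate 2 those of miR-143-3p (0.31), miR-16-5p (0.32), miR-320d (1.41) and miR-7704 (1.45). miR-320b lost its call without any 1 of the EVs untreated replicates (0.87, 0.99 and 0.97) or Cells untreated replicate 1 (1.09). miR-16-5p stood at -0.04 when low counts were not filtered, and the miR-320 list lost its call without Cells untreated replicate 1 or 3, which left 1 list past the threshold.

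SMase-treated EVs and cells differed in the same direction for most miRNAs. miR-320a-3p reached 53468 ± 5972 CPM in SMase EVs against 14905 ± 326 in SMase cells (log2 1.84, SE 0.13, SD of CPM, n = 3 per group, edgeR adjusted p = 2.07e-12). In the let-7 family 8 of 9 members were higher in EVs (8 when adjusted over the list alone; camera adjusted p = 0.00905, adjusted p = 0.35 with an estimated correlation): let-7c-5p by 1.07 (SE 0.12), let-7b-5p by 0.97 (SE 0.12), let-7a-5p by 0.72 (SE 0.13), let-7d-5p by 0.50, let-7f-5p by 0.48, miR-98-5p by 0.42, let-7g-5p by 0.35 and let-7e-5p by 0.35. miR-4455, a riser in SMase cells, stood at 15.4 ± 3.17 CPM in SMase EVs against 850 ± 105 in SMase cells (-5.80, SE 0.42), and miR-21-3p at 224 ± 18.8 against 2384 ± 152 (-3.40, SE 0.20). miR-29a-3p (-2.91, SE 0.15), miR-34a-5p (-2.08, SE 0.15), miR-125b-5p (-1.88, SE 0.16) and miR-21-5p (-1.38, SE 0.15) were lower in EVs.

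Of 264 miRNAs tested, 163 passed, 62 higher in EVs and 101 lower, and in 156 the groups did not overlap. Groups did not overlap for 184 of the 264, where chance gives 10%. Of the calls, 35 were higher both with and without SMase (9.63 expected of independent lists) and 61 lower in both (26.0 expected), with 1 opposite. The compartment differences with and without SMase share no library, though they come from 1 fit and have common scaling, and had r = 0.711 over the 264 miRNAs. Fragment names were again higher in 8 of 9 (8 when adjusted over the list alone; camera adjusted p = 1.15e-08, adjusted p = 0.156 with an estimated correlation), as were 4 of 4 miR-320 members (4 when adjusted over the list alone; camera adjusted p = 0.00448, adjusted p = 0.156 with an estimated correlation), with miR-320c at 2.02, miR-320b at 1.99 and miR-320d at 1.94. miR-4488 stood at 4318 ± 690 CPM against 2.54 ± 4.40, miR-4516 at 6224 ± 1063 against 12.3 ± 5.87, miR-1246 at 1109 ± 332 against 7.25 ± 2.29 and the muscle miRNA miR-1-3p at 1519 ± 1654 against 5.39 ± 3.17. miR-3960 and miR-206, at 0 in SMase cells, were at least 183-fold and at least 28.9-fold higher, the latter uncertain, from 9 counts in SMase EVs. miR-12135 and miR-99a-3p, at 0 in SMase EVs, were at least 23.5-fold and at least 3.66-fold lower.

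No other list passed camera, while 13 lists in all passed fry. The miR-15/16 family had 5 of 7 lower (miR-424-5p -1.62, camera adjusted p = 0.0512), the miR-29 family 3 of 3, hypoxia 6 of 9 (miR-130a-3p -1.30), bone, cartilage and fat 7 lower (miR-31-5p -1.12) and 1 higher (miR-26a-5p 0.83) of 9, inflammation 5 lower and 1 higher of 8, and mesenchymal miRNAs 5 lower (miR-199a-3p -1.05) and 1 higher of 7. The 14q32 cluster had 11 lower and 3 higher of 21, miR-10, miR-99 and miR-125 miRNAs 3 lower and 2 higher of 9, miR-23/27/24 3 of 5 lower (miR-24-3p -0.63), miR-181 2 of 3 lower (miR-181a-5p -0.73), miR-17/92 2 lower and 1 higher of 7, miR-30 3 of 7 higher (miR-30a-5p 0.46), miR-34 1 of 3 lower and export 1 of 4 lower. Adjusted over the list alone the counts were the same, except 3 lower of 3 for miR-34. Under total miRNA counts the median moved by -0.27, and let-7d-5p (0.22), let-7f-5p (0.19), miR-98-5p (0.14), let-7g-5p (0.07) and let-7e-5p (0.07) lost their calls while staying above 0. With piRNA counts in the scaling, where the median miRNA stood at -1.31, 24 miRNAs were higher and 174 lower, 1 of the 62 higher calls became a lower call, and let-7a-5p (-0.01), let-7d-5p (-0.22), let-7f-5p (-0.25), miR-98-5p (-0.30), let-7g-5p (-0.37) and let-7e-5p (-0.38) turned below 0, but miR-320a-3p stayed at 1.11 and let-7b-5p at 0.24. Without EVs SMase replicate 1 the calls of let-7e-5p (0.33), let-7g-5p (0.30) and miR-98-5p (0.35) were lost, and without EVs SMase replicate 2 as well (0.28, 0.32 and 0.43).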

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

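The tests of explanations in this part and the counts of regrouped libraries were chosen only after the results were seen. The test of the difference of effects was planned. The SMase effects on miRNA counts per piRNA count in EVs and cells lay 2.94 apart (log2, exact permutation p = 0.01 for no effect in either compartment, which does not test equal effects). Single miRNAs differed as well: miR-23b-3p by 3.20, miR-99a-5p by 1.76, let-7e-5p by 0.82, miR-320a-3p by 0.80, let-7d-5p by 0.77, miR-31-5p by 0.69, let-7a-5p by 0.65, let-7g-5p by -0.71, miR-3182 by -2.03, miR-4516 by -2.34 and miR-4492 by -2.39. The names over fragments of other RNAs had a median difference of -1.42 (camera adjusted p = 0.000278, adjusted p = 0.992 with an estimated correlation). Among 100 regroupings of the 12 libraries, 5 gave as many single miRNAs as the real 11, and the highest of the others gave 18, so chance is not excluded for that count.

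piRNA names lay outside the miRNA tests and carried a signal of their own. With miRNA and piRNA counts in a single edgeR test, 25 piRNA names were higher and 95 lower in SMase EVs than in untreated EVs. The largest rises were those of piR-32833 at 5.34 (log2, from 35 to 4687 counts summed over 3 libraries), piR-601 at 4.35 (3 to 212), piR-32837 at 3.69 (9 to 376), piR-12654 at 3.30 (2 to 67) and piR-33112 at 2.70 (55 to 1143). Scaled by total counts, 52 were higher and 13 lower. Sequences were not available, so whether these names mark true piRNAs or pieces of other RNAs was not tested.

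The share of miRNAs among EV counts rose after SMase, and leaked cell content may be proposed as a cause. RNA released from broken cells in the proportions the cells hold would give added miRNA counts with the profile of treated cells. Of the 20 most abundant treated-cell miRNAs, 8 were over 2-fold off in every treated EV library (7 lower, 1 higher), and the others were not. This leaves open that such release gave a part of the added counts. The leading piRNA name of cells, piR-33112, rose in SMase EVs from 55 to 1143 counts, a direction that leaked cell content would also give. Added counts were those of a treated EV library minus the mean untreated EV counts scaled to its piRNA total. That assumes a baseline of miRNA per piRNA count that SMase left unchanged, which was not tested. miR-29a-3p made up 3.74% of treated-cell miRNA counts and 0.350% ± 0.0695 of the added EV counts, and miR-320a-3p 1.54% and 4.75% ± 0.284. A loss of the few piRNA names that hold most EV counts is argued against as the whole cause, since miRNA counts per piRNA count outside the 20 most abundant names were 4.78-fold higher (6.74-fold over all names). Selective survival of released RNA, more miRNA per vesicle, and more vesicles over a constant background were not tested and remain open.

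The fall of the fragment names within EV miRNA counts, led by miR-4516 and miR-4488, may be a dilution by the added miRNA counts. Per piRNA count, the median log2 change of the 7 tested members was 0.92 (SD 1.06), above 0 in all 7, against 2.65 (SD 0.670) for the other 103 tested miRNAs. With piRNA counts in the TMM scaling, in contrast, miR-4516 (-0.68, edgeR adjusted p = 0.0358) and miR-3960 (-0.89, adjusted p = 0.0437) were still called lower, and miR-4508 (-0.57) and miR-4488 (-0.11) also lay below 0. Dilution stays open, as does a lower release of these fragments, which was not separately tested.

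More differences of effects lay above 0 (7) than below (4), and the scaling of the shallow untreated EV libraries may contribute. Scaling by total miRNA counts moved all 11 values by -0.27 to -0.22, and 1 of the 7 positive differences kept its call (miR-23b-3p at 2.98), as did 4 of the 4 negative ones (let-7g-5p at -0.94, miR-3182 at -2.30, miR-4516 at -2.60 and miR-4492 at -2.61). Since a common shift by itself fixes which side loses calls, this count does not decide whether scaling is the cause. With no change simulated, the median difference lay at 0.34 under TMM and 0.01 under total miRNA counts, for miRNAs with at least 10 expected counts. In the data the median of all tested miRNAs lay at 0.24 and 0.005. A positive lean under TMM thus arose in simulation without any effect, so scaling alone can give one. The positive differences that lost their calls stayed above 0: let-7a-5p at 0.42, let-7d-5p at 0.54, let-7e-5p at 0.60, miR-31-5p at 0.46, miR-320a-3p at 0.57 and miR-99a-5p at 1.54 (edgeR adjusted p of 0.0614 to 0.117). Selective sorting of these miRNAs was not tested.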

How the results depend on the processing

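Thinned EVs, scaling of all names by total counts, a block across compartments and a test without the fragment names were chosen after the data had been seen, and the other settings before. The cause of a changed count was not tested unless given. miR-143-3p, miR-4455 and miR-21-3p in cells, and let-7g-5p, miR-4488 and miR-4516 in EVs, kept their calls with each scaling, filter, tool and left-out library run on miRNAs alone. With all names miR-21-3p (edgeR adjusted p = 0.0568) and miR-4488 (0.717) lost theirs and let-7g-5p became a higher call (0.45). Of these miRNAs, miR-4488 and miR-4516 alone meet the minimum log2 fold change of 1. The next counts omit that minimum and an adjusted p under 0.1 and, with all names, subtract the median shift. In cells 600 of 713 values of named miRNAs kept a call and its direction or stayed uncalled with either sign (113 weaker). In EVs 584 of 668 did (75 weaker, 9 stronger). For EVs against cells 823 of 894 did without SMase (50 weaker, 17 stronger, 4 reversed). With SMase 987 of 1045 did (37 weaker, 20 stronger, 1 reversed). For the difference 805 of 912 did (85 weaker, 22 stronger). Without that subtraction, 3 of 13 lower calls in EVs became higher calls, and 16 of 41 and 1 of 62 higher calls for EVs against cells became lower calls.

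The 17 calls in cells became 11 with DESeq2 size factors, 6 with total miRNA counts, 11 with upper-quartile factors, 11 with no filter, 7 with a mean CPM of at least 10, 6 with the DESeq2 Wald test, 8 with limma-voom, 4 with all names, 5 with all names by total counts, 2 with the minimum fold change, and 5 with all libraries fitted together. The 20 calls in EVs became 92 with all names, 115 with all names by total counts and 9 with the minimum fold change. The 109 calls for untreated EVs against cells became 229 (12 higher) and 276 (8 higher) with all names. The 163 for SMase EVs against cells became 276 with all names by total counts and 94 with thinned EVs, where fewer counts were left. The 11 differences of effects became 7 with upper-quartile factors, 17 with no filter, 19 (12 negative) with the DESeq2 Wald test, 28 (22 negative) with limma-voom, 112 and 186 with all names, 5 with the minimum fold change and 7 with thinned EVs.

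All names in the scaling moved the median miRNA by 1.20 in EVs, -2.07 for untreated EVs against cells, -0.86 for SMase EVs against cells and 1.20 for the difference. With no filter these shifts were 0.84, -0.77, -0.88 and 0.28. For untreated EVs against cells miR-16-5p then reversed to -0.038, miR-30a-5p to -0.43 and let-7a-5p to -0.51. let-7a-5p also ranged from -0.38 (without EVs untreated replicate 1) to 0.23 with single libraries left out, and miR-16-5p reversed to -0.27 for SMase EVs against cells under total miRNA counts.

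With single libraries left out, calls ranged from 4 to 23 in cells, 6 to 16 in EVs, 97 to 108 and 130 to 152 for EVs against cells without and with SMase, and 3 to 15 for the difference. Passing lists ranged from 0 to 0 in cells, 1 to 1 in EVs, 1 to 3 and 3 to 4 for EVs against cells, and 1 to 1 for the difference. An estimated correlation left 0 lists in each of these, and fry gave 1 in EVs (miR-320, not the fragment names), 15 and 13 for EVs against cells and 5 for the difference. The correlation of effects ranged from -0.134 to 0.149, below 0 without Cells SMase replicate 1 (-0.018) or EVs SMase replicate 2 (-0.021) or 3 (-0.134).

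As shares of all counts, ratios for the 10 most abundant miRNAs became 6.30 in EVs after SMase and 0.0304 and 0.191 for EVs against cells, and those for fragment names 1.90, 7.44 and 12.2. The number of miRNAs with 10 counts had a ratio of 0.943 in EVs and 0.225 for SMase EVs against cells once thinned, and 0.198 for untreated EVs at 20 counts. Left-out ranges, for SMase in cells, SMase in EVs, and EVs against cells without and with SMase, were 0.989 to 0.997, 5.47 to 6.18, 0.0258 to 0.0283 and 0.149 to 0.167 for the miRNA share; 1.00 to 1.01, 1.05 to 1.10, 1.10 to 1.14 and 1.18 to 1.20 for the 10 most abundant; 0.924 to 0.997, 1.91 to 2.07, 0.219 to 0.237 and 0.455 to 0.492 for detection; and 0.998 to 1.34, 0.278 to 0.388, 230.5 to 322, and 66.9 to 89.5 for fragment names.

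Same-number libraries correlated at -0.0549 to 0.180, in no pair of groups all above 0.1. With 3 per group, this cannot decide pairing. A replicate block gave 17, 23, 109, 166 and 10 calls. Regrouping 6 libraries allows 10 splits, too few for a share under 0.05: the real split was the only 1 as large, with 17 against at most 8 in cells, 20 against 1 in EVs, 109 against 0 and 163 against 0 for EVs against cells.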

Other observations

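No tested hypothesis is offered in this part, and the miRNAs and piRNA names below were picked out after their values were seen. The muscle miRNA miR-1-3p had 10, 10 and 7 counts in the untreated EV libraries and 48, 238 and 27 in the SMase EV libraries. The lens and cornea miRNA miR-184 had 12, 29 and 4 counts in untreated EVs and 188, 8 and 3 in SMase EVs, and at most 2 in any cell library. miR-133a-3p, another muscle miRNA, had 0 counts in all 12 libraries.

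Most EV counts carried a few piRNA names. piR-28765 alone held 28.5% ± 1.34 of untreated and 20.8% ± 1.09 of SMase EV counts (SD, n = 3 each), and the 10 most abundant names held 84.6% ± 1.11 and 68.2% ± 2.07. In cells the leading name, piR-33112, held 1.13% ± 0.0218 of untreated counts.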
